A study of Caenorhabditis elegans with 2 samples.

How the data were processed

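Chromatin immunoprecipitation with sequencing was used to map FLT-1 in early embryos of C. elegans. Per the labels, the strain carries an integrated fosmid transgene of flt-1 fused to green fluorescent protein and further epitopes, with unc-119 as the rescue marker. The embryos, aged 1 hour, came from egg bleaching, the chromatin was sonicated to fragments of 200 to 800 bp, and antibody against green fluorescent protein was used. There were 2 biological replicates of 1 group, numbered as in the labels. No control library was used here, although the labels name a possible control experiment.

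The deposited peak lists, 8 in all, are on the ce11 assembly per the file lists that accompany them. These were a thresholded and a ranked list for each replicate, and for both replicates together a pooled thresholded list, a pooled ranked list, a conservative thresholded list and a replicate-against-replicate ranked list. The ranked lists are described in the deposited file lists as ranked by irreproducible discovery rate (IDR), before its threshold. Each thresholded list was made from the ranked list and 1 more file whose content is not given in the sources used here. The peak signal is the authors' value for each peak, with the scale not given in the sources used here; it is never negative and the lists are sorted on it. The deposited score column holds whole numbers up to 1000, and in the pooled ranked list it differed by at most 1 from 125 times the log2 of 1/IDR, when checked on the values. The other ranked lists were not checked in this way. The deposited −log10 IDR column reaches at most 5, and its values were matched to the score by that rule. In the replicate-against-replicate list the authors' columns also hold the signal of each input, of which 61.3% of the first and 57.6% of the second occurred in the list of replicate 1 and of replicate 2. By the rule of the score, which was checked on the pooled ranked list alone, the thresholded lists held no peak above an IDR of 0.01. The aligner, the peak caller and their versions are not given in the sources used here.

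The lists give no read counts, so the depth of each replicate is unknown and no interval that needs a read count was given. Precision is limited by the number of peaks and genes counted. Intervals for shares are exact Clopper-Pearson intervals at 95%, those for odds ratios of Fisher's exact test are exact conditional intervals, those for Mantel-Haenszel odds ratios are normal approximations on the log scale, and all cover counting error only. Since peaks of a pooled list depend on both libraries at once, replicates were compared through their own lists.

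Computations used Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and figures used Matplotlib 3.10.9. Overlaps were counted in Python; the main overlap of the replicates was counted again with bedtools 2.31.1, with a difference of 0 from the first count. Peak positions were set against the WBcel235 sequence, whose chromosome lengths were checked to contain every peak, with gene models of Ensembl release 115. Gene names came from RefSeq with WormBase release WS298, matched by gene identifier for 46881 of 46926 genes. The names were first taken from Ensembl and changed to the RefSeq names after first results had been seen, because some Ensembl symbols were duplicated; Ensembl symbols are kept as an alternative. Coordinates are 1-based.

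The main peak list was the pooled thresholded list of 1083 peaks. Peaks on the mitochondrial genome, 20 in replicate 2, were left out of all genome comparisons. A summit lay in a promoter when it was from 500 bp upstream to 200 bp downstream of an annotated transcript start of a protein-coding gene on a nuclear chromosome, and otherwise in an exon, an intron or intergenic sequence, in that order. The promoter test placed summits at random within their chromosome 1000 times, two-sided. The replicate overlap placed the peaks of replicate 2 in the same way, one-sided, with a minimum overlap of 1 bp. Agreement of signal was described by Spearman's rho and Pearson's r across peaks, with no p. Density per chromosome used an exact binomial test against the share of length and Fisher's exact test on genes with a promoter peak, adjusted by Benjamini-Hochberg over 6 chromosomes. Arms were compared with centres, the middle 50% of each autosome, by Fisher's exact test, as were genes with a divergent neighbour within 1000 bp against other genes. For the closing section, 3 of the gene lists were also compared within gene arrangement, with a divergent neighbour or without, by a Mantel-Haenszel odds ratio and an exact conditional test over both strata, adjusted over the lists, and tRNA genes were compared by copy number of their sequence by Fisher's exact test.

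The 20 gene lists were tested by Fisher's exact test, two-sided, against all other protein-coding genes and adjusted over the lists. They cover nuclear-encoded oxidative phosphorylation, mitochondrial ribosomal proteins, mitochondrial stress response and import, cytosolic ribosomal proteins, aminoacyl-tRNA synthetases, the proteasome, histones, heat shock proteins, maternal, polarity and germ granule genes, zygotic lineage regulators, muscle, intestine and neuronal markers, cuticle collagens and epidermis, chemoreceptors, nuclear hormone receptors, homeobox genes, chromatin modifiers and remodellers, the small RNA pathway, and the cell cycle and spindle. Of the intestine list 19 of 20 names were matched, and of the small RNA list 29 of 30. Non-coding RNA genes of 8 classes were tested by counting summits within 250 bp, with 1000 random placements and adjustment over the classes. Sequence was taken from 200 bp around each summit and compared with promoters that hold no peak, by 1000 random sets for GC content and by Fisher's exact test for 2080 6-mers. Signal was compared between peak classes by a rank-sum permutation test with 100000 resamples, two-sided. The smallest p these can give is 0.001 for placements and 1e-05 for resamples, and 0.05 was the threshold throughout. Only 1 group was present, so no test between groups and no other split of the samples was made.

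The tests, the promoter definition, the gene lists and the rule for named genes were fixed before the data were examined. By that rule the text names the genes nearest to the 15 strongest peaks, up to 4 members with the highest signal of each gene list past its test, flt-1 and unc-119, and the 3 strongest peaks of each RNA class past its test. Alternatives fixed at the same time were the conservative list, the peaks above the median signal, each replicate alone, merged overlapping peaks, peaks at the transgene loci left out, other promoter widths, counting a peak for the nearest gene alone, other gene backgrounds, other overlap rules, other placements, a narrower centre, a distance of 500 bp to RNA genes and a window of 100 bp. Those chosen after the data were seen left out peaks at tRNA genes or at tRNA, snRNA and snoRNA genes, restored peaks at an IDR of 0.01 or below, counted the nearest gene at any distance, used promoter peaks or a background matched in steps of 5% GC, or used Ensembl symbols.

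The procedures were tested on simulated data with known answers. Of 1083 simulated peaks, some were planted in promoters and the rest placed at random, for an expected promoter share of 41.3%. The share recovered was 40.8%, and 1 of 20 random sets passed the threshold. With 20% of peaks planted at tRNA genes, 20.5% were recovered, and 1 of 160 class tests in random sets passed. In a test among 19973 genes, a list with planted members had 12 members with a peak, any drawn at random included. Its exact adjusted p was 1.41e-09, and 0 of 400 lists passed in random gene sets. A planted 6-mer ranked 1 of 2080, with 5 others called, and 0 of 2080 were called in windows drawn from the background. Of 747 simulated peaks, 373 were planted to overlap and 376 were found to. A planted 1.3-fold shift in signal gave a permutation p of 0.0001, the smallest possible there, since fewer resamples were drawn than for the data. No shift gave a permutation p of 0.452. For lists compared within gene arrangement, peaks set by arrangement alone gave 13 of 300 list tests past the threshold, and a planted list gave an exact p of 7.81e-15. In both simulations of gene lists the genes were drawn singly, whereas in the data a peak can count for both genes of a divergent pair. The error rate of the list tests with such sharing was not simulated.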

Results

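The tagged protein was FLT-1, also named BAZ-2, the C. elegans relative of the vertebrate BAZ2 chromatin proteins. It was followed by chromatin immunoprecipitation with sequencing, in which antibody against green fluorescent protein recovered DNA bound by a tagged copy of the protein made from an integrated transgene. The samples were early embryos of 1 hour, in 1 group with 2 biological replicates, so there was no second condition to compare. The question addressed was where FLT-1 lay in the embryonic genome. Peak lists were used for each replicate and for both replicates together, all on the ce11 assembly, which has the WBcel235 sequence. The files gave no read counts, so the sequencing depth of each replicate is unknown. The main list held 1083 peaks called on both replicates together, with a median width of 230 bp and 228.66 kb in all. Peak signal is the authors' value and was used only to rank or describe peaks within a list; it ran from 3.598 to 780 with a median of 75.4. Every 95% interval below is an exact Clopper-Pearson interval for a share or, in Fisher's exact test, an exact conditional one for an odds ratio, and covers counting error only.

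Both replicates marked many of the same places. Replicate 1 had 618 peaks and replicate 2 had 747 on the nuclear chromosomes, and 440 of the latter (58.9%, interval 55.3 to 62.5) were overlapped by a peak of replicate 1. Random placement of the replicate 2 peaks gave 1.84 ± 1.38 (SD over 1000 placements) such overlaps, with a one-sided permutation p of 0.001, the smallest that 1000 placements can give. In the other direction, 441 of 618 replicate 1 peaks (71.4%, 67.6 to 74.9) were overlapped by replicate 2. Of the 1083 main peaks, 434 (40.1%, 37.1 to 43.1) lay over a peak of each replicate and 295 (27.2%, 24.6 to 29.996) over a peak of neither replicate's own thresholded list.

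Signal in the replicates rose together across peaks. Among the main peaks, 1043 had a matching entry in the ranked list of each replicate, and across these peaks Spearman's rho was 0.624 and Pearson's r of the log10 signal was 0.727. The values describe peaks within a pair of libraries; peaks are not independent replicates, and no p is given. Across all 47459 regions of the replicate-against-replicate ranking, most of them below the threshold, rho was 0.227.

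**Figure D1:**
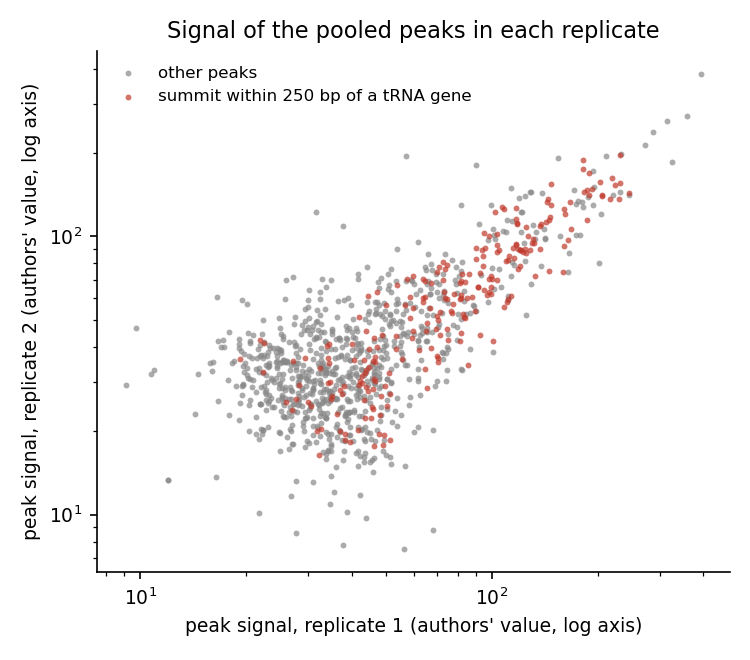
Peak signal in replicate 1 (x axis, the authors' value, log axis) and replicate 2 (y axis, the authors' value, log axis) for the main peaks matched in both replicates; each point is a peak, in red where the summit lay within 250 bp of a tRNA gene and in grey otherwise. Across the 1043 points Spearman's rho was 0.624, and the red points reach high signal in both replicates.

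FLT-1 peaks lay at the starts of protein-coding genes far more often than chance placement would give. Summits in a promoter, from 500 bp upstream to 200 bp downstream of an annotated transcript start, numbered 444 of 1083 (41.0%, 38.05 to 44.0), against 15.9% ± 1.10 (SD) in random placement. That is 2.57 times as many, with a two-sided permutation p of 0.001, the smallest possible here. Exons held 34 summits (3.14%, 2.18 to 4.36) where placement gave 24.0%, and introns held 253 (23.4%, 20.9 to 25.998) where placement gave 30.1%, each with a permutation p of 0.001. The intron call did not hold in replicate 1 alone (28.5%, permutation p of 0.382) or above the median signal (27.5%, permutation p of 0.178). Intergenic sequence held 352 summits (32.5%, 29.7 to 35.4) against 29.9% ± 1.43, a difference with a permutation p of 0.0669; against placement among ranked regions (27.05%), in replicate 2 alone (34.8%) and with promoters of 250 bp on either side (43.0%) it was an excess past the threshold, with permutation p of 0.001, 0.003 and 0.001. With promoters of 1000 bp the intergenic difference reversed its direction. Promoter summits lay at a median of -165 bp from the transcript start, that is upstream of it. They marked 574 genes, 2.87% of the 19973 protein-coding genes tested. The replicates' own lists marked fewer, 302 in replicate 1 and 372 in replicate 2, and 190 genes carried a promoter peak in both of these. Of the 444 promoter summits, 307 lay in 1 promoter, and the remainder lay in several and count for each of those genes.

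**Figure D2:**
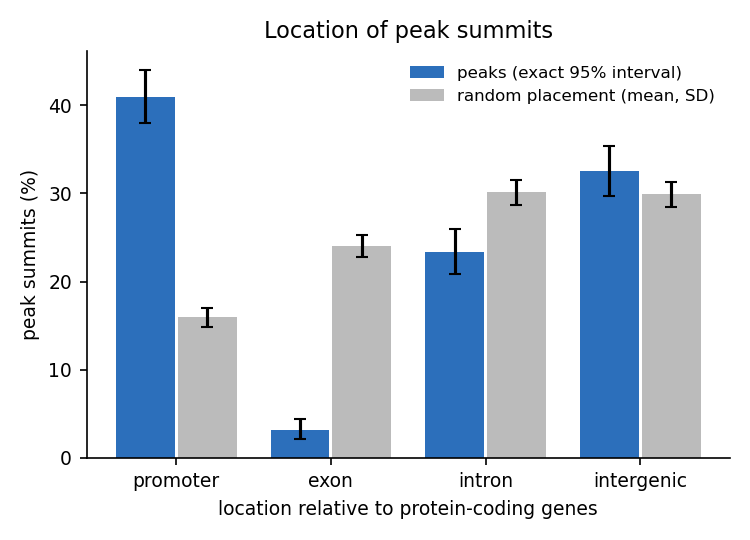
Share of main peak summits (y axis, percent) in promoters, exons, introns and intergenic sequence (x axis); blue bars are peaks with exact 95% intervals and grey bars are random placement with mean and SD over 1000 placements. Promoters held 41.0% of summits against 15.9% in placement, and exons held 3.14% against 24.0%.

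Cytosolic ribosomal protein genes carried a promoter peak at 23 of 78 members (29.5%, 19.7 to 40.9), against 2.77% of other genes. The peaks with the highest signal among them lay upstream of rpl-3 (III:3867496-3867667, signal 271), rpl-15 (IV:654843-655007, 238) and rpl-18A (IV:4750029-4750135, 167), which encode proteins of the large subunit, and rps-28 (IV:1659191-1659300, 159), which encodes a protein of the small subunit. All 4 of these peaks were in both replicate lists. The odds ratio was 14.7 (8.54 to 24.5), with a two-sided Fisher exact adjusted p of 3.58e-16 over 20 gene lists. Replicate 1 alone had 15 members with a peak and replicate 2 alone had 18. Peaks of this list sat upstream of the start, and with a promoter of 250 bp on either side the odds ratio was 3.64, with an exact adjusted p of 0.0608, so the call depends on the promoter width. The odds ratio was 9.16 when each peak counted for the nearest gene alone, 6.31 against genes with a ranked promoter peak, and 3.93 when the nearest gene at any distance was counted, a setting chosen after the data were seen.

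Nuclear genes for oxidative phosphorylation carried a promoter peak at 14 of 74 members (18.9%, 10.7 to 29.7). They included ndua-2 of complex I (I:14113217-14113319, signal 129), cyc-1, the cytochrome c1 of complex III (I:8024584-8024813, 103), cox-5B of cytochrome c oxidase (I:9788595-9788824, 128) and atp-1, the alpha subunit of ATP synthase (I:12652137-12652366, 91.0), each with a peak in both replicates. Their odds ratio was 8.06 (4.13 to 14.7), with a Fisher exact adjusted p of 1.05e-07. Replicate 1 alone had 6 members with a peak (odds ratio 5.84, exact adjusted p of 0.00445) and replicate 2 alone had 8 (6.51, exact adjusted p of 0.000277). The odds ratio of the pooled list fell to 4.76 against genes with a ranked promoter peak and to 3.06 with the nearest gene at any distance, and stayed past the threshold in both. Mitochondrial ribosomal protein genes carried a peak at 5 of 71 members, an odds ratio of 2.57 (0.806 to 6.35) with an exact adjusted p of 0.119. Genes of the mitochondrial stress response and protein import had 3 of 20, among them hsp-6, which is also in the heat shock list, an odds ratio of 5.99 (1.12 to 20.8) with an exact adjusted p of 0.0534. With promoters of 1000 bp both lists passed, at 3.29 (exact adjusted p of 0.0124) and 6.45 (exact adjusted p of 0.0130), and the latter also did without tRNA peaks (exact adjusted p of 0.0455). In replicate 1 alone they were at 1.89 and 3.44 (exact adjusted p of 0.681 for both), and in replicate 2 alone at 0.752 and 0 (exact adjusted p of 1 for both).

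Histone genes carried a promoter peak at 20 of 72 members (27.8%, 17.9 to 39.6). The strongest lay between his-67 and his-68 (I:9988822-9989076, signal 160) and between his-31 and his-32 (IV:8334087-8334210, 98.4), and counted for both genes of each pair; the latter peak was absent from the list of replicate 2. Histone genes have near-identical copies, so the reads behind these peaks are uncertain where copies could share them. The odds ratio was 13.4 (7.54 to 23.1), with a Fisher exact adjusted p of 8.27e-14. Many of these genes share a peak with the other gene of a pair, so the gene is not an independent unit in this test. Replicate 1 alone had 11 members with a peak and replicate 2 alone had 16. Against genes with a ranked promoter peak the odds ratio was 34.5, and it was 5.64 with the nearest gene at any distance. With each peak counted for the nearest gene alone, 12 of 72 histone genes had a promoter peak. That gave an odds ratio of 9.14 (4.44 to 17.3), with a Fisher exact adjusted p of 3.32e-07.

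Heat shock protein genes had a promoter peak at 4 of 24 members, namely hsp-1, a cytosolic HSP70 (IV:17278567-17278656, signal 103), hsp-3, an HSP70 of the endoplasmic reticulum (X:6092107-6092336, 65.4), hsp-90 (V:14685635-14685864, 63.6) and hsp-6, the mitochondrial HSP70 (V:4826988-4827217, 47.3). The peak at hsp-1 was in both replicate lists, that at hsp-90 in replicate 2 alone, and those at hsp-3 and hsp-6 in neither. Their odds ratio was 6.80 (1.68 to 20.4), with a Fisher exact adjusted p of 0.0151. This call did not hold in 6 of 16 alternative settings, among them the peaks of replicate 1 alone, where the odds ratio was 2.84 with an exact adjusted p of 0.681.

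Chromatin modifier and remodeller genes had a promoter peak at 9 of 94 members (9.57%, 4.47 to 17.4). They included swsn-3 of the SWI/SNF complex (III:2768798-2768891, signal 118), set-21 (IV:4390561-4390790, 78.4), jmjd-4 (III:10334024-10334253, 77.2) and set-16, an MLL-type histone methyltransferase (III:13643592-13643821, 75.6). The peaks at set-21 and lin-54 also counted for the ribosomal protein genes rpl-7A and rpl-12. The peak at jmjd-4 also counted for mev-1 of the oxidative phosphorylation list, so these lists are not separate evidence at those peaks. The odds ratio was 3.62 (1.59 to 7.25), with a Fisher exact adjusted p of 0.00611. It was 5.69 in replicate 2 alone, with an exact adjusted p of 0.000277, and 2.16 in replicate 1 alone, with an exact adjusted p of 0.568, so the call rests on replicate 2. The call also ended above the median signal (3.29), with the nearest gene alone (3.07) and against genes with a ranked promoter peak (2.30).

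Chemoreceptor genes, the large family of receptors that sensory neurons use to detect odours and other chemicals, were nearly free of peaks. They had a promoter peak at 3 of 1308 members (0.229%, 0.0473 to 0.669), against 3.06% of other genes, an odds ratio of 0.0728 (0.0150 to 0.214) with a Fisher exact adjusted p of 9.70e-13. The exceptions were srh-269 (V:16592231-16592308, signal 127), whose peak overlay the tRNA gene T03E6.t1, srh-16 (V:12291690-12291919, 120) and sri-5 (I:11182437-11182666, 111). The odds ratio was 0.189 in replicate 1 alone, 0.153 in replicate 2 alone, 0.159 above the median signal, 0.111 with promoters of 1000 bp, and 0.228 both against genes with a ranked promoter peak and with the nearest gene at any distance.

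The other gene lists did not pass the adjusted threshold in the main setting. No promoter peak was seen at 40 maternal, polarity and germ granule genes, 20 muscle markers, 19 intestine markers, 30 neuronal markers or 29 small RNA pathway genes, which allows shares of up to 8.81%, 16.8%, 17.6%, 11.6% and 11.9% by the exact intervals. Cell cycle and spindle genes had 4 of 40 (exact adjusted p of 0.0682), cuticle collagens and epidermis 1 of 174 (0.134), nuclear hormone receptors 4 of 269 (0.363), zygotic lineage regulators 2 of 38 (0.498), aminoacyl-tRNA synthetases 1 of 31 (0.841), the proteasome 1 of 33 (0.841) and homeobox genes 2 of 85 (exact adjusted p of 1). The cell cycle list, with an odds ratio of 3.77 (0.973 to 10.6), passed with promoters of 1000 bp (6.48, exact adjusted p of 0.000396), but was at 1.67 in replicate 1 alone (exact adjusted p of 0.830) and 1.35 in replicate 2 alone (exact adjusted p of 0.756). It also passed narrowly without tRNA, snRNA and snoRNA peaks (4.20, exact adjusted p of 0.0489) and with the nearest gene at any distance (3.45, exact adjusted p of 0.0414).

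**Figure D3:**
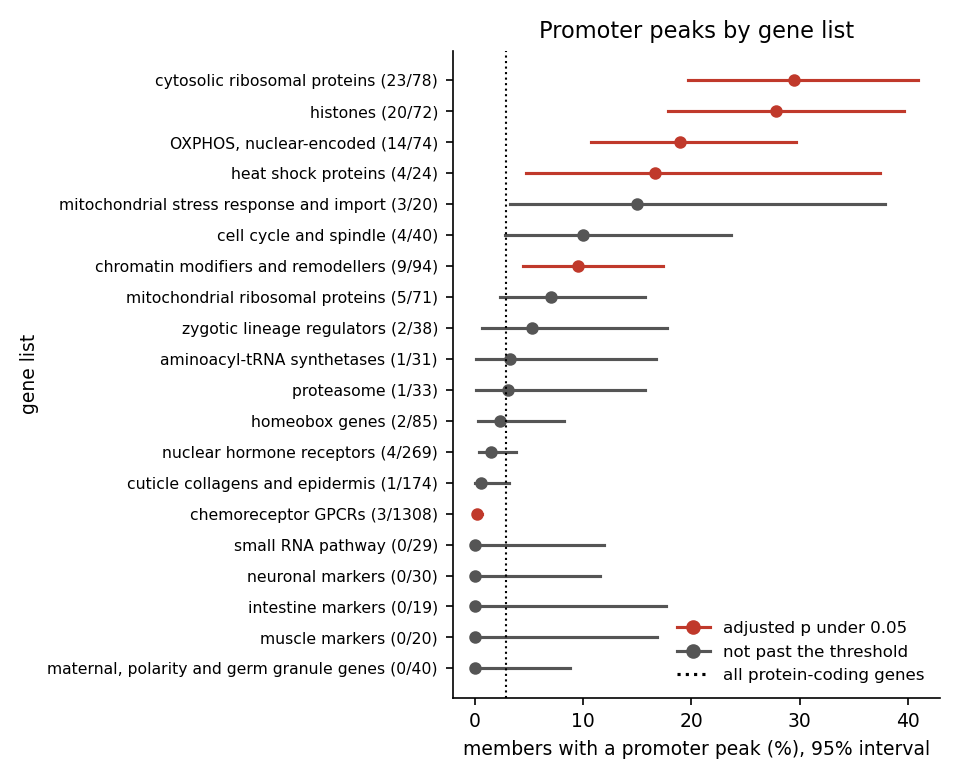
Share of the members of each gene list with a promoter peak (x axis, percent; points with exact 95% intervals) for 20 lists (y axis, with members that have a peak and members measured); red marks an adjusted p under 0.05 in Fisher's exact test and the dotted line is the share of all protein-coding genes, 2.87%. Cytosolic ribosomal proteins, histones and oxidative phosphorylation genes lie at 29.5%, 27.8% and 18.9%, and chemoreceptors at 0.229%.

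tRNA genes, which RNA polymerase III transcribes, were the most enriched feature among the classes tested. Summits within 250 bp of a tRNA gene numbered 251 of 1083 (23.2%), where random placement gave 3.87 ± 1.95 (SD), a ratio of 64.9. The peaks lay at 271 of the 612 nuclear tRNA genes (44.3%, 40.3 to 48.3), and 198 of the 612 had a peak in each replicate's own list. Summits sat close to the 5′ end of the gene, at a median of 15 bp inside it (quartiles 9 and 24), for a median gene length of 72 bp. By signal the leading tRNA genes were C04A11.t1, a leucine tRNA gene in intergenic sequence (X:13665458-13665739, signal 446), F17H10.t1, a glycine tRNA gene in an intron (X:13121215-13121426, 393), and sup-5, a tryptophan tRNA gene in an intron (III:8678454-8678666, 389). Introns hosted 112 of the tRNA peaks, out of 253 intron peaks in all. Signal at tRNA peaks had a median of 131 against 68.9 at the other 832 peaks, with a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. Leaving the distance at 500 bp gave a ratio of 38.1.

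Small nuclear and small nucleolar RNA genes were marked as well. snoRNA genes, which guide modification of other RNAs, had 62 peaks (27.9 times the placement mean), led by C51F7.4 (V:12303502-12303765, signal 780), ZK265.10 (I:8259446-8259692, 632) and W03C9.9 (II:11960694-11960958, 575). snRNA genes had 18 peaks (23.3 times). The leading ones were sls-2.9, of the SL2 spliced leader genes (I:13297637-13297812, 215), whose peak overlay the tRNA gene M01E5.t1, then W05B2.8 (III:10989592-10989791, 182) and C28A5.7 (III:4426910-4426992, 147). miRNA genes had 7 peaks (4.30 times), of which those by mir-51 (IV:11025944-11026342, 535) and mir-52 (IV:14033799-14034210, 259), members of the mir-51 family, and mir-5549 (III:6972044-6972154, 160) had the highest signal. The summit by mir-5549 also lay in the promoters of the protein-coding genes eef-1A.1 and rfc-4. The peak by mir-51 also overlay F36H1.17, the leading member of the broad ncRNA class, which had 310 peaks (6.86 times). That class was followed by T03F7.14 (V:11314075-11314382, 526) and F17H10.8, which lies under the glycine tRNA peak; 128 of the 310 were not near a tRNA, snRNA or snoRNA gene. All of these classes had a two-sided permutation adjusted p of 0.00133 over 8 classes, from a smallest possible p of 0.001.

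piRNA genes, whose 21U-RNAs come from clusters on chromosome IV, had fewer peaks than placement gave, 9 against 35.2 ± 5.12 (SD), with a permutation adjusted p of 0.00133. The leading ones, by 21ur-5229 (IV:5967109-5967244, signal 212), 21ur-3939 (IV:16382428-16382558, 146) and 21ur-2860 (IV:16684331-16684560, 126), each overlay a tRNA gene. The ratio was 0.256, against 0.471 in replicate 2 alone. lincRNA genes had 5 peaks (1.36 times, permutation adjusted p of 0.664), and the 20 annotated rRNA genes had 0 (permutation adjusted p of 1). Other settings moved the ratios within these classes without ending a call. At 500 bp they were 13.1 for snRNA, 16.4 for snoRNA, 4.47 for ncRNA and 0.385 for piRNA. Replicate 1 alone gave 7.78 for miRNA, replicate 2 alone gave 35.4 for snRNA, and the peaks above the median signal gave 46.2 for snoRNA.

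Within the main list, most of the strongest peaks lay at these RNA genes. The list leaves out 15 of the 20 strongest peaks at an IDR of 0.01 or below, and 0 of all 175 left out lay near a tRNA gene, so the ranking holds for the main list alone. Among the 15 peaks with the highest signal, 14 lay within 250 bp of a tRNA, snRNA or snoRNA gene, and all 15 were in both replicate lists. The exception was the peak by mir-51. The nearest protein-coding transcript starts were those of F55C5.17, sre-23, W03C9.1, hrg-5, cutl-18, str-56, C04A11.5, pxn-1, T02E1.2, Y43F8C.7, snx-17, pgl-2, cat-1, K07H8.7 and col-181, in order of signal. Only T02E1.2 had the summit in its promoter (I:8224295-8224551, signal 422, 459 bp upstream), and that summit lay 61 bp from the snoRNA gene T02E1.9. The nearest start was far away for pxn-1 (5684 bp) and K07H8.7 (6964 bp), so these names give position and not a target. Together, 329 peaks (30.4%) lay near a tRNA, snRNA or snoRNA gene, and 722 (66.7%) lay either there or in a protein-coding promoter.

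Peaks were unevenly spread over the chromosomes. Chromosome X had 246 peaks, 13.9 per Mb, which is 1.29 times its share of the sequence (1.15 to 1.43; exact binomial adjusted p of 7.06e-05 over 6 chromosomes). Chromosome III had 190, 1.28 times its share (exact binomial adjusted p of 0.000957), and chromosome V had 144, 0.637 times its share (exact binomial adjusted p of 8.16e-10). Chromosomes I, II and IV were at 1.04, 1.02 and 0.868 times, with exact binomial adjusted p of 0.629, 0.735 and 0.068. X also carries 276 of the 612 tRNA genes (45.1%), and without the tRNA peaks, a setting chosen after the data were seen, its ratio was 0.952 (0.812 to 1.11, exact binomial p of 0.555), while III was at 1.39 and V at 0.685. tRNA genes on X had a peak at 117 of 276 (42.4%, 36.5 to 48.5) and those on autosomes at 154 of 336 (45.8%, 40.4 to 51.3), an odds ratio of 0.870 (0.623 to 1.21) with a Fisher exact p of 0.414.

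**Figure D4:**
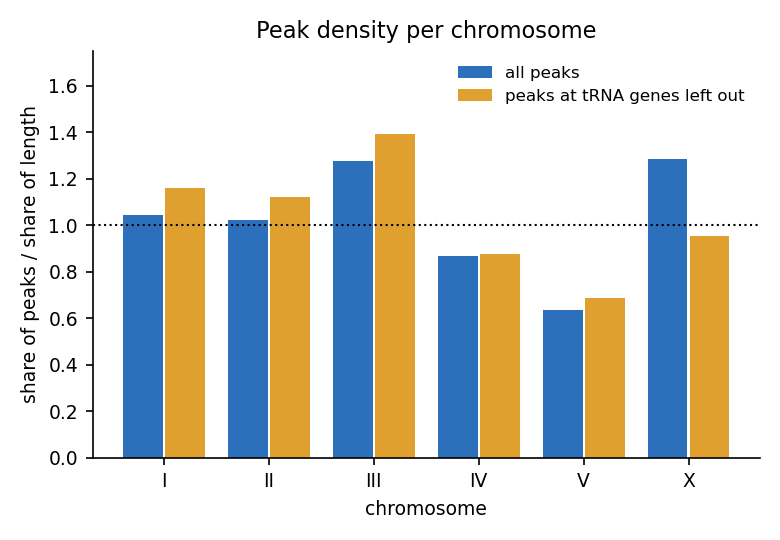
Share of main peaks on each nuclear chromosome (x axis) divided by its share of the sequence length (y axis, ratio); blue bars are all peaks, orange bars leave out peaks with a summit within 250 bp of a tRNA gene, and the dotted line is 1. Chromosome X stands at 1.29 with all peaks and at 0.952 without the tRNA peaks, and chromosome V at 0.637 and 0.685.

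Counted over genes, the promoters with a peak were more frequent on chromosome I (117 of 2878 genes, odds ratio 1.54, Fisher exact adjusted p of 0.000166) and chromosome III (112 of 2640, 1.62, exact adjusted p of 5.77e-05). They were less frequent on chromosome V (96 of 4994, 0.595, exact adjusted p of 9.13e-06). Genes on X had 67 of 2731, an odds ratio of 0.830 (0.631 to 1.08) with an exact adjusted p of 0.262; above the median signal it was 0.531, past the threshold with an exact adjusted p of 0.00607. Genes on II had an odds ratio of 0.936 (exact adjusted p of 0.614) and those on IV had an odds ratio of 0.919 (exact adjusted p of 0.592). The gene-rich centres of the autosomes and their arms were alike within counting error, with promoter peaks at 285 of 9597 centre genes (2.97%) and 222 of 7645 arm genes (2.90%), an odds ratio of 1.02 (0.853 to 1.23) with a Fisher exact p of 0.821. A summit in several promoters counts for each of those genes, so the gene is not an independent unit in these tests by chromosome, arm and centre.

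Divergent gene pairs were favoured. Genes with a divergent neighbour whose start lay within 1000 bp had a promoter peak at 298 of 3539 (8.42%), against 276 of 16434 other genes (1.68%). The odds ratio was 5.38 (4.53 to 6.39), with a Fisher exact p of 7.75e-80. A peak between such genes counts for both, so the gene is not an independent unit in this test.

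The sequence under the summits was rich in G and C. The 200 bp around the 1083 summits had a mean GC content of 46.2% ± 6.65 (SD over peaks), against 35.3% in promoter windows without a peak, with a two-sided permutation p of 0.001, the smallest possible. Without the peaks at tRNA, snRNA and snoRNA genes the mean was 45.6%, and in promoter peaks 44.9%. Of 2080 6-mers, 1444 differed from the background windows in Fisher's exact test after adjustment, 822 of them more frequent and 622 less frequent in peaks. The leading ones were CGAACC (21.5% of peaks against 3.17%, exact adjusted p of 1.04e-102) and GTTCGA (25.8% against 6.95%, exact adjusted p of 1.95e-72). Against windows matched on GC content, chosen after the data were seen, 660 6-mers differed, now with 387 less frequent and 273 more frequent in peaks, and GTTCGA (25.8% against 7.94%) and CGAACC (21.5% against 6.19%) still led. The matched background held 1083 windows in place of 19399, so the lower number of 6-mers cannot be put down to GC content alone. With the peaks at tRNA, snRNA and snoRNA genes also left out, 425 differed between 754 peaks and 754 background windows, 284 less frequent and 141 more frequent. The leading ones were then ACGCGC (17.1% of peaks against 5.30%), CGCACA (19.8% against 7.03%) and ACACAC (22.4% against 8.89%), and no longer GTTCGA or CGAACC.

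Promoter peaks had slightly lower signal than the rest, a median of 72.8 at 444 peaks against 79.1 at 639. The difference of -6.35 had a two-sided permutation p of 0.00707. Its direction depended on the RNA genes: with peaks at tRNA, snRNA and snoRNA genes left out, promoter peaks stood 8.31 higher (70.9 at 393 peaks against 62.5 at 361, permutation p of 2e-05), and with tRNA peaks alone left out 4.82 higher (permutation p of 0.0327). With every peak class kept, it was -16.96 in replicate 1 alone, -31.3 above the median signal, -13.3 with all peaks at an IDR of 0.01 or below, -10.3 in the conservative list, -9.93 with promoters of 1000 bp and -5.69 with promoters of 250 bp on either side.

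No main peak lay at the loci duplicated in the transgene. The flt-1 gene (III:7650553-7656032, listed as baz-2) with 20 kb on either side had 0 peaks, where the genome-wide density gives 0.491, and unc-119 (III:10902641-10908935), the rescue marker, with 5 kb on either side had 0, where 0.176 is given. With expected numbers below 1, these counts of 0 exclude little. In the pooled ranked list, before any threshold, the regions held 4 and 12 entries, where density gives 21.8 and 7.82, with a highest signal of 24.2 and 33.015.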

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

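The tests with tRNA, snRNA or snoRNA peaks left out, those with left-out peaks restored, the use of the replicates (an alternative itself fixed beforehand) to test the excess on chromosome X, the comparison of lists within gene arrangement, the comparison of tRNA genes by copy number, the comparison with proteasome and synthetase genes and the demand that it hold in each replicate, and the question of a control immunoprecipitation were chosen only after the result was seen. Data outside the main comparisons held 2 signals of note. Replicate 2 alone had 20 thresholded peaks on the mitochondrial genome, with a median signal of 212 and a highest signal of 881, where replicate 1 and the pooled list had 0. The pooled ranked list held 175 peaks at an IDR of 0.01 or below that the thresholded list leaves out, with a median signal of 133 against 75.4 in the peaks kept and a maximum of 3028 (X:15810960-15811202), and they include 15 of the 20 strongest; 2 of them lay in promoters, 0 near a tRNA gene and 2 near an rRNA gene.

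Chromosome X held 1.29 times its share of peaks by length. The excess is not accounted for by the peaks the authors left out, since with them restored the ratio was 1.27 (exact binomial p of 1.76e-05), nor by 1 replicate, since the lower of the ratios of the replicates was 1.23 (exact binomial p of 0.00395). Without tRNA peaks the ratio was 0.952, and tRNA genes had a peak about as often on X (42.4%) as on autosomes (45.8%). The density of tRNA genes on X is therefore a candidate explanation of the whole excess. No biological explanation was tested, since the design has 1 group.

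Of all main peaks, 23.2% lay at tRNA genes. Reads shared between genes of identical sequence do not account for all of this, since tRNA genes whose sequence occurs once in the genome had a peak at 31.4% (23.9 to 39.8), nor do neighbouring promoters, since peaks outside protein-coding promoters were 58.1 times the random mean (permutation p of 0.001). Reads shared with near-identical copies were not tested. Shared reads may account for a part, since genes with 6 or more copies had a peak at 49.1% (44.0 to 54.2), an odds ratio of 2.105 (1.38 to 3.25) against single-copy genes with a Fisher exact p of 0.000341; other differences between these genes were not tested. A signal that any immunoprecipitation gives at these highly transcribed genes cannot be told apart from binding by FLT-1, since 0 control libraries were used here. No biological explanation was tested.

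Promoters of ribosomal protein, histone and oxidative phosphorylation genes held peaks more often than other promoters. RNA genes beside them do not account for it, since without the peaks at tRNA, snRNA and snoRNA genes the lowest odds ratio of the 3 lists was 8.98 (4.60 to 16.4), nor does counting a peak for both genes of a divergent pair, since with each peak counted for 1 gene it was 6.28 (2.73 to 12.8). Divergent arrangement does not account for all of it: compared within arrangement, oxidative phosphorylation genes had a Mantel-Haenszel odds ratio of 4.28 (approximate interval 2.36 to 7.76), histones 5.13 and ribosomal proteins 7.64, with exact adjusted p of 1.7e-05 or lower, though each was below its value over all genes (8.06, 13.4 and 14.7), oxidative phosphorylation genes had 2.41 (0.890 to 5.63) among divergent genes and 14.99 (5.48 to 35.5) among others, and outside divergent pairs histones had a peak at only 1 of 10 (exact p of 0.156). In the comparison within arrangement, 1 peak can count for both genes of a histone pair, so histone genes are not independent units there. Proteasome and synthetase genes had a promoter peak at 1 of 64 (1.56%, 0.0396 to 8.40) in replicate 1, where the margin was smallest. Ribosomal protein and histone genes were there at 15.3% or more, so these 64 broadly expressed genes had peaks less often. The 64 genes come from lists picked after the result was seen, and other broadly expressed genes were not set beside them. Histone pairs can also share a peak. The comparison therefore cannot decide whether broad expression is the only cause for ribosomal protein and histone genes. The 64 genes were also not matched on divergent arrangement, so broad expression, alone or together with arrangement, stays open. For oxidative phosphorylation genes broad expression alone stays open as well. The pooled 3.12% (0.381 to 10.8) lay under their 18.9%, while in each replicate the interval, up to 8.40% and 13.1%, reached their 8.11% and 10.8%. The very high transcription of these genes stays open, because no expression or control library was used here, and no biological explanation was tested.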

How the results depend on the processing

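The alternatives that leave out tRNA, snRNA or snoRNA peaks, restore peaks at an IDR of 0.01 or below, count the nearest gene at any distance, use promoter peaks, use Ensembl symbols or match GC content were chosen only after the result was seen. Of 279 values for the main comparisons, 257 were the same, 12 kept direction without the call, 6 reversed and 4 moved. With a test, the same means that direction and side of the threshold were kept. A value without a test, such as a count, was the same when close to that of the main setting and had moved otherwise. Of 369 details, 322 were the same, 2 lost a call, 12 gained one and 33 reversed, and for named peaks 378 values were the same and 14 had no peak. The cause was not tested for any change below unless the setting itself shows it. Depth is unknown, so its effect could not be weighed. Replicate overlap and signal agreement need both replicates, so neither was recomputed with 1 left out. No paired analysis was possible because there is 1 group.

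Promoter share (28.8 to 52.1%), divergent pairs (4.27 to 6.14), GC excess and the ratios of chromosomes III (1.24 to 1.41) and V (0.628 to 0.686) kept their calls in every alternative run, as did oxidative phosphorylation (3.06 to 8.98), histones (5.64 to 34.5), chemoreceptors (0.0516 to 0.228) and the 6 RNA classes. Without tRNA, snRNA and snoRNA peaks the ratio of X was 1.04, and without tRNA peaks 0.952; promoter signal was 8.31 and 4.82 higher. Ribosomal proteins fell to 3.64 with 250 bp promoters. Heat shock proteins were at 3.38 in the conservative list, 3.19 above the median signal, 2.29 with 250 bp promoters, 4.07 with the nearest gene alone and 1.77 at any distance. Chromatin modifiers were at 3.29 above the median signal, 3.07 with the nearest gene alone and 2.30 against ranked promoters. Arms against centres was 0.991 in the conservative list, 0.892 with 250 bp promoters and 0.948 with a narrower centre, none past the threshold. GC matching, which also left 1083 background windows in place of 19399, gave 660 6-mers. Signal agreement was 0.696 in the conservative list and 0.227 over all ranked regions. All 977 peaks of the conservative list are in the replicate-against-replicate ranked list. They were chosen by agreement between replicates, so the higher value there is partly set by that choice.

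With 1 replicate left out, values ran from 2.84 to 7.58 for heat shock proteins, 2.16 to 5.69 for chromatin modifiers, 618 to 747 for peaks, 0.915 to 1.08 for the ratio of chromosome I, 0.924 to 1.01 for II, 0 to 3.41 for the proteasome, 0 to 1.43 for lineage regulators, 0.752 to 1.89 for mitochondrial ribosomal proteins, 0 to 3.44 for mitochondrial stress and import, 0 to 1.35 for maternal genes, 1.35 to 1.67 for cell cycle genes and 0.473 to 1.95 for lincRNA.

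The lost calls among the details were the intron share above the median signal (27.5%) and in replicate 1 alone (28.5%). Calls gained were the intergenic share in replicate 2 alone (34.8%), with 250 bp promoters (43.0%), among ranked regions (32.5%) and with restored peaks (41.2%); X genes above the median signal (0.531); with 1000 bp promoters, mitochondrial ribosomal proteins (3.29), mitochondrial stress and import (6.45) and cell cycle genes (6.48); without tRNA, snRNA and snoRNA peaks, mitochondrial stress and import (6.66) and cell cycle genes (4.20); without tRNA peaks, the former (6.38); and at any distance, the latter (3.45).

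Other reversals were of values not past the threshold in the main setting. In the conservative list, lineage regulators were at 0, muscle markers at 1.95 and lincRNA at 0.895. Above the median signal, chromosome II was at 0.981, and the proteasome, lineage regulators and cell cycle genes were at 0. With restored peaks, chromosome II was at 0.981 and rRNA at 9.13, there past the threshold (permutation adjusted p of 0.0251). With 1000 bp promoters, intergenic share was 25.02%, chromosome II genes 1.01, synthetases 0.857 and the proteasome 0.803. With 250 bp promoters, mitochondrial stress and import and the proteasome were at 0. The nearest gene alone gave homeobox genes 1.08. Against ranked promoters, synthetases were at 0.729 and the proteasome at 0.555; against named genes, 0.860 and 0.806. At any distance, synthetases were at 0.648, the proteasome at 0.608, muscle markers at 2.17, intestine markers at 1.08 and neuronal markers at 2.17.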

Other observations

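The names of genes outside the fixed rule and the tests on the peaks outside promoters and RNA genes were chosen only after the result was seen. Among lineage regulators, the peaks were at hlh-1, the muscle MyoD relative (signal 62.9, in replicate 2 alone), and nhr-25, a nuclear receptor of epidermal development (47.3, in neither replicate list). Of the cell cycle list, which passed with promoters of 1000 bp and not in the main setting, the genes were mdf-1 of the spindle checkpoint (66.5), cdc-6 of replication licensing (61.6), sas-6 of centriole assembly (56.6) and klp-7, a kinesin (45.8), of which only mdf-1 had a peak in a replicate's own list, that of replicate 1.

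A group of 361 peaks lay neither in a promoter nor near a tRNA, snRNA or snoRNA gene. Of these 224 were intergenic, 108 in introns and 29 in exons, with a median signal of 62.5 and a mean GC content of 46.8%. Peaks in both replicate lists made up 90 of them (24.9%), and 145 were in neither. They lay near miRNA genes 6 times (11.0 times the random mean) and near ncRNA genes 76 times (5.10 times), each with a permutation adjusted p of 0.004, and near a piRNA gene 1 time (0.0770 times, permutation adjusted p of 0.00533).

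tRNA genes of different amino acids were marked at shares from 61.5% of 13 cysteine genes to 31.6% of 19 tyrosine genes. No difference among 20 isotypes was detected by a permutation test over 606 genes (p of 0.873). Isotypes had from 12 to 55 genes, so differences between them are not excluded. By copy number of the sequence, the share was 31.4% (23.9 to 39.8) of genes that occur once, 43.4% (32.5 to 54.7) of those with 2 to 5 copies and 49.1% (44.0 to 54.2) of those with 6 or more.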
